A study of Sus scrofa with 4 samples.

How the data were processed

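Total RNA was extracted from pools of porcine blastocysts, amplified with a RiboAmp kit and labelled directly with Cy3 or Cy5 through a non-enzymatic chemistry that binds guanine, per the labels' protocols. Each of the 4 arrays carried NEFA RNA in 1 channel and control RNA in the other, per the labels, and was treated as 1 pool of each. The deposited scanner files hold the median pixel intensity of each spot and of its local background at 532 nm (Cy3) and 635 nm (Cy5), per the file headers, and had not been normalised. The scanner and image software are not given in the sources used here. The submitters' processing notes name limma, with no version or steps. The authors' deposited table of processed values holds log2 ratios for 43795 rows that match the scanner spot numbers. Set against the scanner values, its columns correlated at r = 0.967 to 0.995 with log2 Cy5 over Cy3 after background subtraction and loess, with slopes of 0.975 to 1.04. That comparison gives the scale as log2 and the direction as Cy5 over Cy3 on all 4 arrays, not turned for the dye swap. Its column medians were -0.020, -0.023, -0.022 and -0.023. How its centring was done remains unknown.

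Each array had 45220 spots, of which 1426 were control spots, 1 layout mark included, and 43794 were probes, each spotted once. Spot intensities were corrected with normexp (offset 50, fitted on all spots) and normalised by loess within each array, with control spots at weight 0. Between 35 and 75 probes per array carried a scanner flag and were left out on that array. Saturated spots were kept: 0 in Cy3 on each array and 2 to 42 in Cy5. A probe was kept if it exceeded the mean plus 2 SD of the 153 negative control spots of its array and channel in at least 3 of the 4 pools of 1 condition, which left 17145 probes. Median raw intensities of probes ran from 289 to 436 in Cy3 and from 220 to 289 in Cy5, against a local background of 31 to 42 and of 46 to 71. The limits set by the negative controls were 237.0 to 369 in Cy3 and 201 to 306 in Cy5. They apply to intensities after normexp with its offset, so they are not on the scale of the raw medians. Between 38.3% and 49.0% of probes exceeded the limit in a channel, so many probes were not above background. Ratios of dim probes are pulled toward 0 by the offset.

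Gene names came from the platform annotation, which can be old. It gave 1 symbol for 13146 probes (10024 symbols) and several for 0, and 30648 probes are unnamed here. Of the symbols, 9857 were found in the current pig gene table (assembly Sscrofa11.1), which was used for names only. No coordinates are given, as no genome build is named for the array. A gene with several probes was represented in list tests by the kept probe with the highest mean log2 intensity and no flagged spot.

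Log2 ratios were fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, using a dye intercept and a NEFA term coded by the dye orientation in the labels. This leaves 2 residual degrees of freedom, to which eBayes added 3.67 prior degrees of freedom. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the kept probes. Dye orientation was the batch in the design. Slide and scan date were not used here. Before the data were examined, 38 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 measured genes (34 of 38) were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. A count of probes at an unadjusted p under 0.05 and 1.5-fold describes the ranking and is not controlled for multiple tests.

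Named genes were to be up to 12 in each direction past the adjusted threshold with the largest change and the same direction on 4 of 4 arrays. Where fewer passed, places were filled by the smallest unadjusted p among named probes with at least 1.5-fold change in the same direction on 4 of 4 arrays, and only 3 higher and 8 lower genes qualified. The member with the smallest p in each list and a panel of 23 genes of lineage, lipid metabolism, stress and chromatin were named whatever their result. Of the panel, 12 had a named probe and 9 were measured. A probe above background in no pool of a condition has only a bound, from the mean of the brighter condition against the higher of the dim probe's own signal and the lowest signal above background, per channel after loess and Aquantile.

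The probe test was tested on simulated data made from the fitted dye effects of 17073 probes, with 200 probes changed. Variances were drawn from the prior that eBayes fitted, and noise was independent between probes. It recovered 16% of the 2-fold and 90% of the 4-fold changes of NEFA over control, with 5 false calls among 111. The list test, on 4686 genes, called a list shifted by 0.5 on the log2 scale at an adjusted p of 2.12e-13 and 0 other lists. That shift exceeds the mean of every tested list here, the largest being 0.14 for fatty acid uptake and transport. Probes on the real arrays share patterns that the simulated noise lacks, so the simulations do not measure the error rate or power in these data. Alternatives were no background correction, an offset of 10, median centring, Aquantile between arrays, no filter, no dye term, an intensity trend with a robust prior, array weights, the authors' deposited log2 values, the mean of a gene's probes, and each array left out in turn. Correlations between arrays over different probes of the same gene used 768 genes with at least 2 kept probes, with 10000 permutations of the gene pairing. Intervals of correlations across probes came from 200 bootstrap resamples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.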

Results

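Gene expression was measured in porcine (Sus scrofa) blastocysts, the embryo stage at which an outer trophectoderm encloses an inner cell mass. The blastocysts came from oocytes exposed to a high level of non-esterified fatty acids (NEFAs), the free fatty acids that circulate when body fat is mobilised, or from control oocytes. The question put by the design was whether exposure of the oocyte left a difference in the transcripts of the embryo. Each of 4 two-colour oligonucleotide arrays compared RNA of blastocysts from exposed oocytes with RNA of control blastocysts. The design names 4 pools of 10 blastocysts collected on days 7 and 8, without saying whether these are 4 per condition or whether each pool mixed both days. The NEFA pool carried Cy3 on arrays 1 and 2 and Cy5 on arrays 3 and 4. The labels number the 4 arrays as biological replicates, and each array is treated here as 1 NEFA pool against 1 control pool. Nothing in the labels says whether the pools came from separate cultures, so p-values measure only the spread between these arrays. Between 38.3% and 49.0% of the 43794 probes were above background in a channel. The 17145 probes kept for testing included 5702 with a gene symbol, for 4705 genes. Values below are log2 ratios of NEFA over control from a limma fit with a dye term, given as mean ± SE with n = 4 arrays unless an SD is named, and the small number of arrays limits their precision.

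With the dye orientations given in the labels, blastocysts from NEFA-exposed and control oocytes did not differ detectably in any transcript. The limma fit called 0 of 17145 probes at an adjusted p of 0.05, and the smallest adjusted p was 1.00 after rounding. This count depends on the labelled orientations: with those of arrays 2 and 3 exchanged, an alternative chosen after seeing the data, 1193 probes passed, with 0 gene lists past the camera threshold. At an unadjusted p under 0.05 there were 264 probes, or 1.54% of those tested, where 5% would be reached on average with no difference at all. Shared patterns between probes make this count vary widely: other splits of the same arrays gave from 108 to 3197 probes. Of these, 52 probes also differed by at least 1.5-fold, 26 toward NEFA and 26 toward control, and 11 of them had a gene symbol. With the orientations of arrays 2 and 3 exchanged the split was 869 toward NEFA and 181 toward control. Exchanging arrays 1 and 4 instead is its mirror image, with the same counts and every direction turned round. The directions given for the exchanged fit, here and below, are therefore not fixed by the data. With the labelled orientations, the higher side held 22 of 32 such probes with no background correction and 28 of 81 with median centring. Only 6 probes had a mean difference of 2-fold or more. The direction was the same on all 4 arrays for 7.82% of probes, below the 12.5% that chance gives for independent arrays with no dye bias. A preference of a probe for 1 dye would lower that reference. The median probe had a 95% interval of ± 0.40 on the log2 scale, a factor of 1.32. The count of 52 rose with each array left out: it was 152 without array 1, 383 without array 2, 335 without array 3 and 85 without array 4. Those fits have fewer residual degrees of freedom and estimate the variance anew, so a higher count can come from the variance as well as from the ratios. The values of 34 of the 56 genes named below moved by over 1.5 times when 1 array was left out, and those of 6 (SCD, GATA6, BAX, HSPA5, ATR and SLC2A8) did so toward 0 with median centring.

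Among named genes at least 1.5-fold apart and in the same direction on 4 of 4 arrays, 3 had higher and 8 had lower signal in the NEFA pools. None passed the adjusted threshold. On the higher side were DOPEY2 at 0.90 ± 0.14, KIAA2018 at 0.71 ± 0.16 and TRIOBP, an actin-binding protein, at 0.64 ± 0.28. DOPEY2 was at 0.04 and KIAA2018 at 0.19 with no background correction, and at 3.43 and 3.04 in the authors' deposited table. Both probes were above background in 3 of 4 NEFA pools and 2 of 4 control pools, so they were kept through the NEFA pools alone. TRIOBP rested on array 4, where it was 1.86 against 0.06 to 0.41 on the others, and its mean was 0.23 without that array. DOPEY2 was 1.74 and 1.64 on the arrays with NEFA in Cy3 but 0.21 and 0.00 on those with NEFA in Cy5. KIAA2018 was 0.13 and 0.24 on the former and 0.91 and 1.56 on the latter. The dye term takes up these gaps, so the SEs are small beside SDs over the 4 arrays of 0.92 for DOPEY2 and 0.66 for KIAA2018. On the lower side was GNPDA2, a deaminase of glucosamine phosphate, at -0.99 ± 0.18, and at -0.09 with no background correction. Its probe was above background in 1 of 4 NEFA pools and 3 of 4 control pools, and 1 other probe of the gene had the opposite sign. MED1, a subunit of the Mediator complex that bridges transcription factors and RNA polymerase, had a value of -0.78 ± 0.23. The immediate early transcription factor FOS stood at -0.69 ± 0.19 and WTAP, a subunit of the RNA adenosine methyltransferase complex, at -0.66 ± 0.15. ZCRB1, a splicing factor, and CD47, a surface protein that inhibits phagocytosis, were both at -0.64, with SEs of 0.14 and 0.16. For CD47, 1 of 3 probes had the opposite sign. SECISBP2, needed for selenoprotein synthesis, was at -0.62 ± 0.24 with -1.67 on array 4 and a mean of -0.29 without it, and AIG1 at -0.59 ± 0.15. The adjusted p in limma was 1.00 after rounding for each of these 11 genes. This ranking holds for the labelled orientations. With those of arrays 2 and 3 exchanged, 0 of the 11 genes reached 1.5-fold and 4 changed sign, DOPEY2 to -0.03, WTAP to 0.13, AIG1 to 0.05 and MED1 to 0.02, and GNPDA2 was at -0.25.

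**Figure D1:**
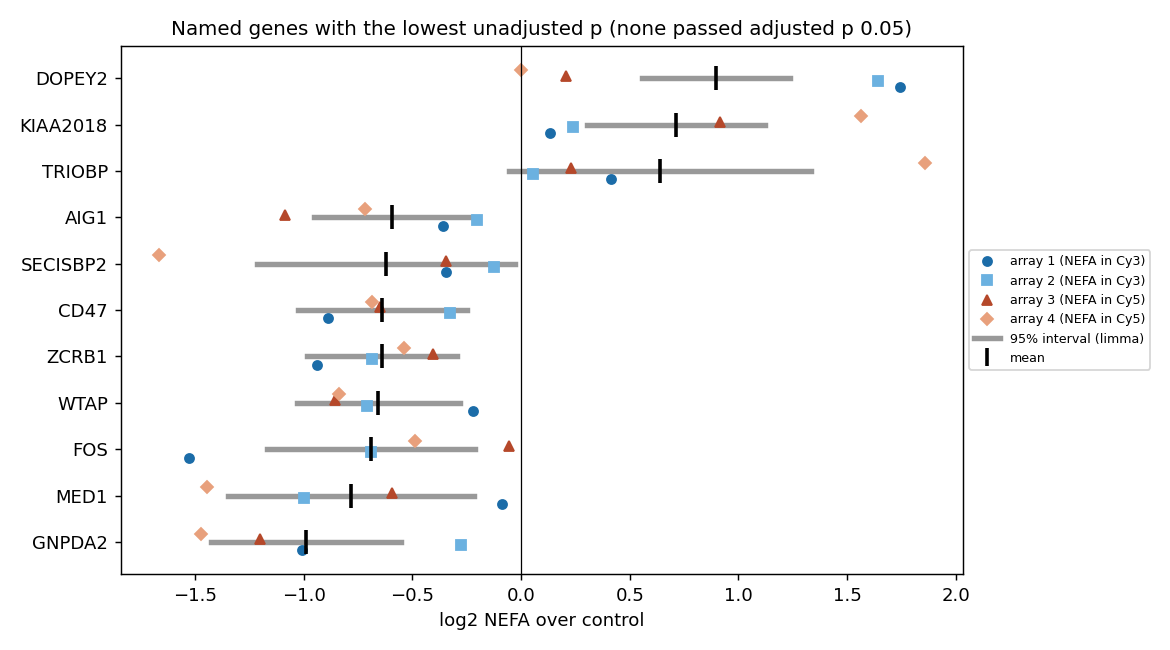
Log2 ratio of NEFA over control (x axis) on each of the 4 arrays for 11 named genes (y axis), with the limma mean as a tick and its 95% interval as a grey bar. The genes are those at least 1.5-fold apart and in the same direction on 4 of 4 arrays. DOPEY2 lies at 1.74 and 1.64 on arrays 1 and 2 and at 0.21 and 0.00 on arrays 3 and 4, and no gene passed the adjusted threshold.

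Genes of fatty acid handling, the processes closest to the exposure, did not pass any test. Among 18 measured genes of fatty acid oxidation, 9 had values above and 9 below 0, and the smallest p belonged to ACSL3, which activates long-chain fatty acids, at 0.49 ± 0.18 (higher on 4 of 4 arrays). Of 6 genes of fatty acid uptake and transport 5 were above 0, and the list median was 0.14 ± 0.13 (SD, n = 4). FABP5, a fatty acid-binding protein, averaged 0.54 ± 0.34 but ranged from -0.59 on array 4 to 1.54 on array 3, and averaged 0.01 without array 3. The lipid droplet list had 9 of 14 genes below 0, with a median of 0.10 on array 1 and of -0.14 to -0.13 on the others. Its members included PLIN2, the main coat protein of lipid droplets, at -0.22 ± 0.14 (lower on 4 of 4 arrays), and CIDEB at -0.35 ± 0.15. In fatty acid synthesis, 3 of 8 genes were above 0, with ACLY, which makes cytosolic acetyl-CoA, at 0.32 ± 0.21 (0.10 without array 2 and 0.54 without array 1). SCD, the main desaturase, was at 0.09 ± 0.14 with 2 saturated channels. Cholesterol synthesis had 8 of 9 genes above 0, a list median of 0.16 ± 0.27 (SD, n = 4) and HMGCS1 at 0.47 ± 0.24 (0.14 without array 4). The list's mean of 0.13 was -0.02 without array 2 and -0.05 with the orientations of arrays 2 and 3 exchanged. The camera adjusted p of the cholesterol list was 0.355 with the preset correlation and 0.900 with an estimated correlation. It was 0.00313 without array 1, and then 0.815 with an estimated correlation. For nuclear receptors that bind lipids and their targets, 4 of 8 genes were above 0, with NR1H3 at 0.27 ± 0.15, although 1 of its 2 probes had the opposite sign. With the orientations of arrays 2 and 3 exchanged, ACSL3 was at -0.30, FABP5 at -0.51, ACLY at -0.06 and NR1H3 at -0.06. PLIN2, CIDEB, SCD and HMGCS1 kept their sign. The list means then changed sign for oxidation, uptake (to -0.13), lipid droplets and cholesterol synthesis, and kept it for fatty acid synthesis and the nuclear receptors.

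Of the blastocyst's cell lineages, only the trophectoderm and primitive endoderm lists had enough measured genes to test, and neither passed (camera adjusted p = 0.961 each). Of 15 measured trophectoderm genes 9 had values above 0, and the list's median was -0.06 ± 0.20 (SD, n = 4). ELF5, a transcription factor of the trophoblast lineage, was not above background in any of the 4 NEFA pools and was above it in 3 of 4 control pools. Its probe therefore gives only a bound on the measured means, 1.18-fold or more higher in control, with the limma adjusted p at 1.00 after rounding. The bound carries no interval, and the probe was kept through the control pools alone, so it does not establish a difference. With the orientations of arrays 2 and 3 exchanged the limma value of ELF5 was -0.02. GATA3, another trophectoderm regulator, was at -0.35 ± 0.21. Its probe and that of APOA1, given next, were above background in 2 of 4 NEFA pools and 3 of 4 control pools. In the primitive endoderm list 6 of 12 genes were above 0, with APOA1 at -0.32 ± 0.19 (-0.10 without array 1 and -0.54 without array 2) and GATA6, a regulator of that lineage, at 0.10 ± 0.18 (-0.09 without array 2). Inner cell mass and epiblast genes were too few to test, with 3 of 13 listed on the array measured, IL6ST among them at 0.16 ± 0.14. The IL6ST probe was above background in 3 of 4 NEFA pools and 1 of 4 control pools. The signals of early elongation were likewise not tested, with 2 of 8 measured and TGFB3 at 0.44 ± 0.22. SOX2, CPT1A and DNMT3B had probes that were not kept. POU5F1, NANOG, CDX2, KRT8, SOX17, PPARGC1A, DNMT1, IGF2, H19, IGF2R and SLC2A1 had no probe under these symbols among the named probes used here. Genes of junctions and cavitation, which form the fluid-filled cavity, had 11 of 16 values above 0. Their list median was 0.09 ± 0.31 (SD, n = 4) with 0.54 on array 4, and AQP11 was at -0.38 ± 0.14.

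Markers of other cells that a pool could hold were followed in the same way. Of 22 cumulus and granulosa genes on the array 10 were measured, with a list median of -0.07 ± 0.16 (SD, n = 4) and FST, an activin-binding protein, at -0.46 ± 0.23. Oocyte and maternal transcripts had 9 of 20 measured and 7 of these above 0, with a list median of 0.09 ± 0.19 (SD, n = 4) and the oocyte growth factor GDF9 at 0.31 ± 0.15. Sperm genes had 3 of 13 measured, a list median of -0.52 on array 4 and of -0.09 to -0.06 on the others, and ODF2 at -0.26 ± 0.17 (SE). The ODF2 probe was above background in 1 of 4 NEFA pools and 3 of 4 control pools. The camera adjusted p was 0.794 for the cumulus and 0.590 for the oocyte list.

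Genes of energy metabolism had values on both sides of 0. Of 32 nuclear-encoded genes of oxidative phosphorylation 14 were above 0, with COX6C, a subunit of cytochrome c oxidase, at 0.31 ± 0.14. The tricarboxylic acid cycle had 7 of 11 genes below 0, a list median of -0.15 ± 0.28 (SD, n = 4) and IDH3B, a subunit of mitochondrial isocitrate dehydrogenase, at -0.49 ± 0.20 (lower on 4 of 4 arrays). Glycolysis and glucose transport had 4 of 6 genes above 0, and its list median ran from -0.62 on array 4 to 0.48 on array 2. SLC2A8, a glucose transporter, was at 0.24 ± 0.15. For mitochondrial biogenesis and dynamics 7 of 14 genes were below 0, with PINK1, a kinase of mitochondrial quality control, at -0.26 ± 0.14. In the pentose phosphate list 5 of 6 genes were below 0, with RPIA at -0.37 ± 0.27. The camera adjusted p was 0.630 for the tricarboxylic acid cycle and at least 0.699 for the other lists of this group. No gene of the mitochondrial genome had a named probe used here.

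Stress, death and immune genes showed no difference past the threshold. In the unfolded protein response list 12 of 21 genes were above 0. CALR, a chaperone of the endoplasmic reticulum, was at -0.43 ± 0.15 and HSPA5, the main such chaperone, at 0.18 ± 0.15, with HSPA5 at -0.60 on array 1 and 0.70 on array 3. Heat shock proteins had 8 of 11 genes above 0 and a camera adjusted p of 0.528 with the preset correlation and 0.900 with an estimated correlation. DNAJA1, a co-chaperone, was at 0.31 ± 0.20. In oxidative stress defence 11 of 17 genes were below 0, with SOD2, the mitochondrial superoxide dismutase, at -0.27 ± 0.17 and KEAP1, which restrains the antioxidant response, at -0.25 ± 0.15 with -0.63 on array 1. For apoptosis and p53 genes 7 of 14 were above 0. GADD45G was at 0.37 ± 0.14 (higher on 4 of 4 arrays), BAX, which promotes apoptosis, at 0.11 ± 0.26 (-0.17 without array 1 and -0.13 without array 4), and BCL2L1, which opposes it, at 0.53 ± 0.41. BCL2L1 ranged from -0.88 on array 2 to 2.20 on array 4, and its mean was 0.02 without array 4. BAX and BCL2L1 were the 2 named genes that passed in limma with the orientations of arrays 2 and 3 exchanged, at 0.52 (adjusted p = 0.0455) and 0.90 (adjusted p = 0.0304). That orientation was chosen after seeing the data, and 1193 of 17145 probes passed with it. Exchanging arrays 1 and 4 instead would make both values negative. These p-values therefore do not test an effect of NEFA on the 2 genes. In the inflammation list 6 of 10 genes were below 0, with the chemokine IL8 at -0.39 ± 0.17. Interferon response had 6 of 9 genes above 0 and STAT2 at -0.26 ± 0.18. Autophagy and lysosome genes had 8 of 15 values below 0 and BECN1 stood at -0.36 ± 0.20. Of the hypoxia genes 6 of 12 were above 0, with VEGFA at 0.40 ± 0.16.

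Chromatin, growth and housekeeping genes did not pass either. Of 5 measured genes of DNA methylation and demethylation 4 were below 0, with TET1, which oxidises methylcytosine, at -0.19 ± 0.18 (0.02 without array 4). Histone modifiers had 8 of 14 values below 0 and CARM1 stood at 0.31 ± 0.21, with 1 of its 2 probes of opposite sign. In one-carbon metabolism 4 of 6 genes were above 0, with MTRR, which reactivates methionine synthase, at 0.39 ± 0.14 (higher on 4 of 4 arrays). The MTRR probe was above background in 4 of 4 NEFA pools and 2 of 4 control pools. Imprinted genes had 4 of 7 values below 0 and DIRAS3 at -0.28 ± 0.14. For insulin and mTOR signalling 6 of 11 genes were above 0, with PRKAA2, a catalytic subunit of AMP-activated kinase, at -0.36 ± 0.19. The smallest p of any list was that of the cytosolic ribosomal proteins, with 25 of 33 genes above 0, a mean of 0.07 and RPL9 at 0.30 ± 0.19. Its camera adjusted p was 0.20 with the preset correlation and 0.900 with an estimated correlation. The mean of the ribosomal list was below 0 under median centring and without array 2, and was -0.12 with the orientations of arrays 2 and 3 exchanged. Without array 1 its camera adjusted p was 0.000194, and 0.815 with an estimated correlation. Translation factors had 13 of 21 values below 0 and a list median of -0.23 on array 1, with EIF3D at -0.38 ± 0.19 and 1 of its 2 probes of opposite sign. The proteasome had 12 of 23 above 0 with a list median of -0.26 on array 4 and PSMA3 at -0.33 ± 0.17, the cell cycle 12 of 23 below 0 with AURKA at -0.28 ± 0.15, and DNA damage repair 10 of 15 below 0 with ATR at 0.16 ± 0.14.

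Across all 34 tested lists, 0 passed a camera adjusted p of 0.05 and 3 had an unadjusted p under 0.05, those of ribosomal proteins, cholesterol synthesis and heat shock proteins. With an estimated correlation 0 lists had an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move on balance one way, gave a smallest adjusted p of 0.953, and its test for changes in either direction also passed 0 lists. No member of any list passed over all probes, and 0 passed when adjusted over the list alone. The median, the mean and the camera direction did not share a sign in 10 of the 34 lists. With the orientations of arrays 2 and 3 exchanged, 18 of the 34 list means and 15 of the 56 named genes had the other sign, and the smallest camera adjusted p was 0.389. The mean changed sign under at least 1 change of background correction or scaling in 12 lists: trophectoderm, fatty acid oxidation, fatty acid synthesis, oxidative phosphorylation, unfolded protein response, apoptosis, one-carbon metabolism, histone modifiers, insulin signalling, ribosomal proteins, proteasome and hypoxia.

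**Figure D2:**
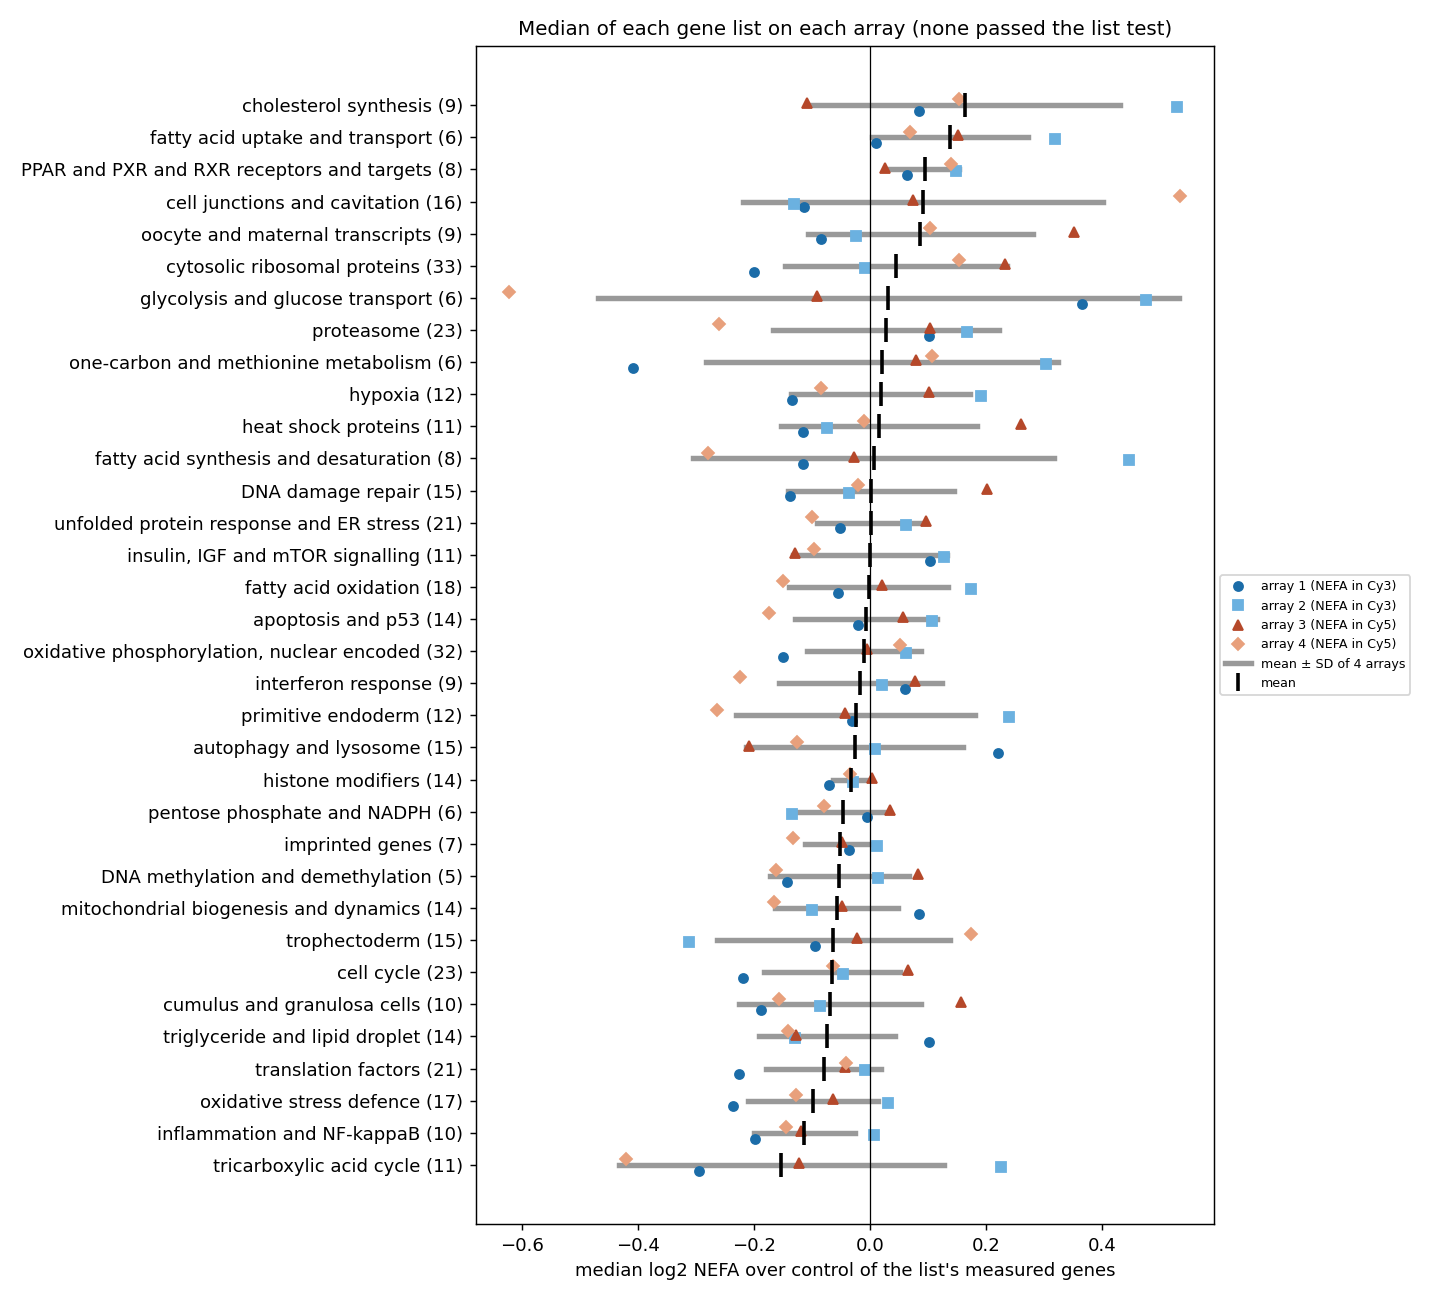
Median log2 ratio of NEFA over control (x axis) of the measured genes of each of the 34 tested lists (y axis, number of genes in brackets) on each of the 4 arrays, with the mean of the 4 medians as a tick and ± 1 SD as a grey bar. The mean runs from -0.15 for the tricarboxylic acid cycle to 0.16 for cholesterol synthesis, and no list passed the camera test.

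The ratios of the 4 arrays did not share 1 direction across genes. Across the 17145 probes, which are not independent replicates, the log2 ratios of NEFA over control correlated at r = -0.54 between arrays 2 and 4, -0.29 between arrays 1 and 3 and -0.24 between arrays 1 and 2. The other pairs had r = 0.01 for arrays 2 and 3, 0.15 for arrays 1 and 4 and 0.16 for arrays 3 and 4. Among the brightest 25% of probes the r between arrays 2 and 4 was -0.71. Arrays 1 and 2 carry the same dye orientation and correlated at r = -0.03 over all 43794 probes. The dye orientation was taken from the labels throughout.

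**Figure D3:**
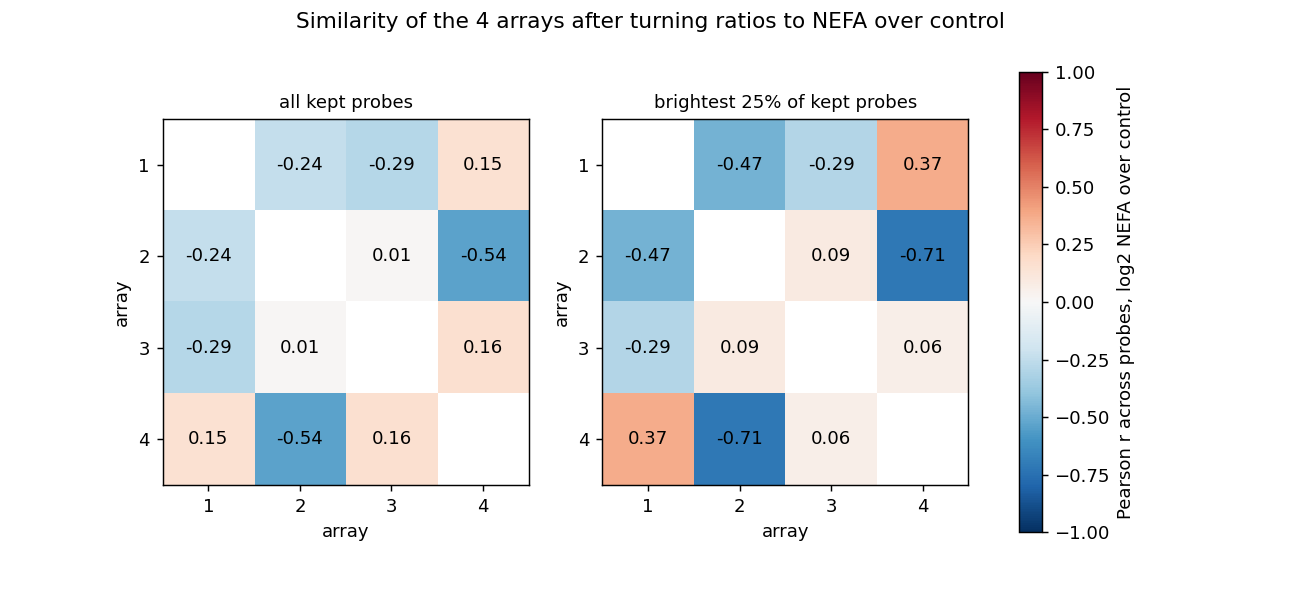
Pearson r across probes (colour and number) between the log2 ratios of NEFA over control on each pair of the 4 arrays, for all 17145 kept probes (left) and the brightest 25% of them (right). The r for arrays 2 and 4 is -0.54 on the left and -0.71 on the right.

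The preference of single probes for 1 dye was estimated in the same limma fit. No probe had a dye effect at an adjusted p of 0.05, with 0.698 the smallest adjusted p, and 1121 probes (6.54%) had an unadjusted p under 0.05. The median absolute dye effect was 0.16 on the log2 scale, against 0.11 for the median absolute ratio of NEFA over control. Among the named genes, the dye estimate of Cy5 over Cy3 was -0.79 for DOPEY2, 0.64 for BCL2L1 and 0.53 for KIAA2018.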

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

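The 93 groups of 4 array values (named genes and list medians, as log2 ratios of NEFA over control) were searched for 1 array far from the other 3, by the gap to its nearest neighbour over the range at the limit for 4 values. Chance alone gives about 1 in 20, and 6 were found. Array 1 stood apart in 3 of them. KEAP1 was -0.63 on array 1 and -0.15 to -0.08 on the others. The triglyceride and lipid droplet median was 0.10 on array 1 and -0.14 to -0.13 on the others, and the translation factor median was -0.23 on array 1 against -0.04 to -0.01. Array 4 stood apart in the other 3. SECISBP2 was -1.67 there against -0.35 to -0.12, the proteasome median was -0.26 against 0.10 to 0.17, and the sperm median, over 3 genes, was -0.52 against -0.09 to -0.06. No explanation of these single values was tested.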

How the results depend on the processing

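The count of probes past the adjusted threshold rests on the dye orientations in the labels: with those of arrays 2 and 3 exchanged, an alternative chosen after seeing the data, it was 1193, with 1050 probes at an unadjusted p under 0.05 and 1.5-fold and 0 lists past the camera threshold. With the labelled orientations it was 0 under each setting, each left-out replicate included, except with the authors' deposited log2 values, which gave 2: GNPDA2 at -4.66 and SEC14L2 at -3.98, the latter named after its value was seen. Both lie near background. On arrays 3 and 4 the deposited ratios were -8.22 and -9.30 for GNPDA2 and -8.27 and -7.19 for SEC14L2, against -0.99 and -0.75 for the means after normexp. With no background correction GNPDA2 was at -0.0875. The count at an unadjusted p under 0.05 and 1.5-fold, 52 as reported, was 32 with no background correction, 82 with an offset of 10, 81 with median centring and 81 with no filter. It was 12 in the brightest 25% of probes, an alternative chosen after seeing the data that tests 4286 probes, and ranged from 85 to 383 with a replicate left out. The share of these probes that was higher in NEFA was 50%, but 68.8% with no background correction, 34.6% with median centring, 33.3% in the brightest 25%, and 27.7% to 75.3% with a replicate left out. Lists past the camera threshold ranged from 0 to 2 with a replicate left out, and were 0 otherwise. The 2, cholesterol synthesis and cytosolic ribosomal proteins without replicate 1, had adjusted p-values of 0.0935 to 0.983 and 0.0671 to 0.983 in the reported fit and the other alternatives, and without replicate 1 an adjusted p of 0.815 each with an estimated correlation. The dye effect called 0 probes in each setting tried. Exact sign flips of the 4 arrays allow 8 patterns with mirrors joined, too few for a share under 0.05. Each array holds NEFA and control RNA, so the fit on ratios is already paired by array.

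The 56 named genes and 34 lists, none called, had 1268 alternative values, but many of these could not change. Aquantile, no filter, no dye term, an intensity trend and array weights left the values of genes such as TET1, GATA6 and BAX as they were. An estimated correlation and fry do not alter the mean of a list. Of the 1268 values, 57 had the other sign, 53 of them with a shift within 1 SE (gene) or 1 SD (list). The others were TET1, which ranged from -0.401 to 0.0187 (without replicate 4), GATA6, from -0.0948 (without replicate 2) to 0.303, BAX, from -0.175 (without replicate 1) to 0.392, and the mean of the histone modifier list at -0.0572 under median centring. The cause was not tested for any of these shifts. Under the 5 changes of background or scaling 0 named genes and 12 lists changed sign, but sizes moved: 4 of 54 named genes moved by over 1.5 times with no background correction (DOPEY2 to 0.0351, KIAA2018 to 0.190, GNPDA2 and BCL2L1), 4 of 56 with deposited values, 6 of 56 with median centring (SCD to 0.0183, GATA6 to 0.0175, BAX to 0.0335, HSPA5 to 0.0976, ATR to 0.0796 and SLC2A8 to 0.157) and 34 of 56 when a replicate was left out. Signal over background limits all of this: 77 kept probes were above background in no NEFA pool and 121 in no control pool.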

Other observations

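The tests of dye bias, of exchanged orientation and of other splits were chosen after the correlations between arrays and the counts had been seen. The test of a spatial trend was read on a pair of arrays known from those correlations, so it was not framed independently of them.

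The largest pattern in these arrays did not follow the treatment as labelled. After each probe's mean Cy5 over Cy3 was taken off, 63.4% of the remaining variance lay along 1 component, with array scores of 0.69, -0.38, 0.25 and -0.57 for arrays 1 to 4, and 22.9% lay along the contrast of NEFA with control. None of the 34 gene lists followed this component, and the smallest adjusted p, that of the tricarboxylic acid cycle, was 0.262. In Cy5 over Cy3, arrays 2 and 4 correlated at r = 0.54 across probes, with 0.18 in the dimmest 25% of probes and 0.71 in the brightest. The other pairs did not all go this way: arrays 3 and 4 had 0.42 in the dimmest and 0.06 in the brightest, and all 6 pairs lay between 0.13 and 0.42 in the dimmest. Between different probes of the same gene, over 768 genes, the relation held for 3 of 6 pairs and for none with array 3. The r was 0.13 (adjusted permutation p = 3e-04) for arrays 2 and 4, -0.11 (adjusted p = 3e-04) for arrays 1 and 2, and -0.09 (adjusted p = 4e-04) for arrays 1 and 4. It was 0.01 for arrays 1 and 3 and for arrays 3 and 4 (adjusted p = 0.8 each) and 0.02 for arrays 2 and 3 (adjusted p = 0.6). The unadjusted p of 1e-04 behind the first 2 is the smallest that the permutations can give. The permutations treat genes as independent, so genes that vary together can make these p-values too small. Within an array the r between probes of a gene was 0.15 to 0.28.

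Dye bias of single probes, shared by all arrays, would make Cy5 over Cy3 correlate above 0 on each pair. Arrays 1 and 2 gave r = -0.24 over the kept probes (bootstrap interval -0.26 to -0.22) and -0.03 over all probes. The interval resamples probes as if independent and does not measure spread between arrays. The r of -0.24 argues against dye bias as the whole pattern among kept probes. It leaves dye bias open for the dimmest 25% of probes, where all 6 pairs were above 0. A spatial trend across the array is argued against by the r of arrays 2 and 4, which was 0.53 after the median of each block of 10 by 10 spots had been taken off. An exchange of the dye orientation of arrays 2 and 3, or its mirror image in arrays 1 and 4, remains open as a hypothesis. The array scores above, which set arrays 1 and 3 against 2 and 4, would then follow the treatment, in a direction that depends on which pair was exchanged. For NEFA over control on arrays 2 and 4, either exchange would make the r of -0.13 between different probes of the same gene positive. However, arrays 1 and 3, which would then share an orientation, had an r of only 0.01 across different probes. The pairs of array 3 with arrays 2 and 4 had 0.02 and 0.01. On the same probes, Cy5 over Cy3 of arrays 1 and 3 had r = 0.29, the sign that an exchange calls for. Arrays 3 and 4, which would then differ in orientation, had r = 0.16, against the sign that it calls for. A wrong orientation of array 2 alone stays open as well. Across different probes it would likewise make NEFA over control correlate above 0 for each pair among arrays 1, 2 and 4. It would leave arrays 3 and 4 at r = 0.16, but arrays 1 and 3 at r = -0.29, against the sign that it calls for. Its split gave 0 probes past the adjusted threshold and 594 at an unadjusted p under 0.05 and 1.5-fold. A difference between pools that does not follow the treatment, such as the day of collection (7 or 8), stays open and was not tested.

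The 4 arrays allow 7 splits into signs that the fit with a dye term can take, too few for a share under 0.05. The labelled split gave 0 probes past the adjusted threshold, a count that all 7 splits must reach, and the highest other gave 1193. At an unadjusted p under 0.05 and 1.5-fold the labelled split gave 52, where 6 of the 7 gave as many and the highest other gave 1050. Both highest counts came from the split that sets Cy5 over Cy3 of arrays 1 and 3 against that of arrays 2 and 4, the grouping that the correlations above already show, so these counts restate that structure and are no further evidence for it. That split is the contrast of NEFA with control if the orientations of arrays 2 and 3, or in the opposite direction those of arrays 1 and 4, were exchanged. The counts do not say which reading holds, since a difference between pools in another respect would give the same split.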
